A study of Mus musculus with 4 samples.

How the data were processed

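The series holds 4 two-colour arrays of genomic DNA from 3T3-L1 cells, 1 each for control and shRNA8 cells at day -2 and day +2. Per the labels' protocols, 1 µg of DNA per sample was labelled with Cy5 for the immunoprecipitated fraction and with Cy3 for input. The input label of shRNA8 cells at day +2 gives that day but describes the cells as not yet induced, and it was taken as day +2. The authors deposited the output of Agilent Feature Extraction 11.0.1.1, per the file headers, which also name the genome build, mm9. The deposited intensity columns hold, for each spot and channel, the median signal, its background, the background-subtracted signal and a processed signal that is dye-normalized, per the file headers. A deposited log10 ratio of the processed signals and a deposited p-value for that ratio accompany each spot, and the p-value was not used. The submitters' processing notes name limma without saying what it was used for. All 4 arrays were scanned together on 1 slide, with shRNA8 cells in positions 1 and 2 and control cells in positions 3 and 4.

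For each probe the log2 ratio of the processed Cy5 to the processed Cy3 signal was taken. Probes marked as saturated, non-uniform or a population outlier in either channel of any array were left out, which kept 174301 of 174638 probes. Probes not above background in the input of all 4 arrays were also left out, which kept 95060, or 54.4%. The ratios were centred on each array's median and quantile normalized across the 4 arrays, which removes any difference in overall methylation between samples. Probes up to 1000 bp apart formed a region, and a region needed at least 3 probes. A region counted as higher or lower when the mean difference of its probes was at least 0.6 on the log2 scale (1.52-fold) and at least 75% of its probes moved that way. No test was made, as each group has 1 array. An additive fit of line and day over the 4 arrays would leave 1 residual degree of freedom, with their interaction as the error, and was not run. For chance, 2 references were used. In the first, probes were shuffled among regions within 10 classes of input brightness, 100 times, and in the second, for the counts per window of 2 Mb, the called regions were placed at random, 100 times. Neither stands for the variation between cultures.

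The rule for regions named in the text, fixed before the data were examined together with the thresholds and alternatives, takes, among regions that counted as higher or lower, the 8 with the largest positive and the 8 with the largest negative difference between the lines at each day, the 4 of each sign for each day change, and the 6 of each sign with the largest smaller difference at both days. It was written for promoter regions and for genes. The files pair probes with coordinates and not with genes, and the gene table given for this work is of GRCm38, another build than the arrays' mm9. The rule was therefore applied to all regions, and the 14 gene lists and the location classes fixed beforehand were not analysed here. Windows of 2 Mb, the regions they hold and the input bins were examined after the values were seen. The tests of methylated DNA at first used correlations of adjacent probes, that of DNA copies used windows chosen on the ratio, and the split by level used all 4 arrays. These decided nothing or were tied to the differences themselves, and the ones reported replaced them after their values were seen.

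The script for regions was tested on simulated data, made by shuffling the real differences and adding known ones to 50 regions per size among 17452. An added difference of 1 was recovered in 92% of regions between the lines at each day, in 94% between the days in control cells and in 98% between the days in shRNA8 cells. For an added difference of 0.5 this was 36% and 34% between the lines at day -2 and day +2, and 30% and 26% between the days in control and shRNA8 cells. A simulated adjacent-probe correlation of 0.3 came out as 0.302.

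The alternatives were median centring alone, scaling to one median absolute deviation, a within-array loess of the ratio on mean intensity (limma), the deposited log ratio, no filter, at least 5 probes, size rules of 1 and 0.4, all probes moving the same way, the median of probes, removal of a loess trend on the level, and autosomes alone. Median spot signals without background subtraction, a stricter background filter, removal of trends on probe length and input brightness, the IP channel alone and the brightest 20% of probes were added after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.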

Results

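Methylated DNA was profiled by immunoprecipitation with an antibody against 5-methylcytosine followed by hybridization to a tiling array of promoter-sized segments of the mouse genome (MeDIP-chip). The cells were 3T3-L1, a mouse embryo fibroblast line that is committed to the fat lineage and turns into adipocytes when induced. The wild type line served as control. The other line stably carried an shRNA, named shRNA8, directed against slincRAD, a long non-coding RNA. Each line was sampled at day -2, before induction, and at day +2, after 2 days in medium with 0.5 mM 3-isobutyl-1-methylxanthine, 1 µM dexamethasone and 167 nM insulin. There were 4 arrays, 1 for each line and day, and none had a replicate. No difference below could be set against a spread between replicates, no p-value is given, and the number of arrays limits the precision. The SD given with a region is the spread over its probes on the same pair of arrays. MeDIP-chip does not measure RNA, so the level of slincRAD itself could not be checked.

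Each array carried 174638 genomic probes on 19 autosomes and the sex chromosomes. The immunoprecipitated DNA (IP) was labelled with Cy5 and the input DNA with Cy3, an assignment that follows the labels and was not checked. An exchange of the 2 would turn every direction given below. The median IP signal after background subtraction was 56.1 at day -2 and 56.5 at day +2 in shRNA8 cells, and 49.1 and 48.9 in control cells. The input channel was dimmer, with medians of 8.64 and 8.78 in shRNA8 cells and 6.49 and 5.95 in control cells, over a background of 22 to 26. The share of probes whose input lay well above background was 39.2% and 41.6% in shRNA8 cells and 34.8% and 35.7% in control cells. Probes above background in the input of all 4 arrays numbered 95060, and they formed 17452 regions of at least 3 probes, with a median of 5 probes and a median width of 1349 bp. Regions are named by their mm9 coordinates, since no gene annotation of that build was used here.

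The 4 arrays gave nearly the same profile. The log2 ratio of IP to input correlated between any 2 arrays with Pearson's r of 0.935 to 0.951 across probes. The IP channel correlated with r of 0.998 to 0.999 and the input channel with r of 0.955 to 0.967. In all arrays the ratio also depended on probe length, with medians of 0.02 to 0.05 for probes of 45 bp and -1.49 to -1.23 for those of 60 bp. The agreement between arrays therefore does not by itself stand for a shared methylation profile. The SD of the IP differences between arrays was 0.11 to 0.14 on the log2 scale in the 4 comparisons, and that of the input differences was 0.51 to 0.57. Input therefore made up 93.5% to 96.3% of the variance of the 2 channels' differences, so that a lower ratio in the comparisons below mostly stands for a brighter input. Single spots also varied within an array. The 208 repeat spots of one control probe (net signal of 20.4 to 25.5 in IP and 10.7 to 20.3 in input) had an SD of 0.12 to 0.14 in IP. Their SD in input was 0.54 and 0.26 in shRNA8 cells and 0.64 and 0.39 in control cells at day -2 and day +2. These are SDs of single spots of one probe and do not compare directly with SDs of differences between 2 arrays. The median ratio of an autosome lay between -0.09 and 0.09 around the array median in each array, and that of chromosome X between -0.13 and -0.06.

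**Figure D1:**
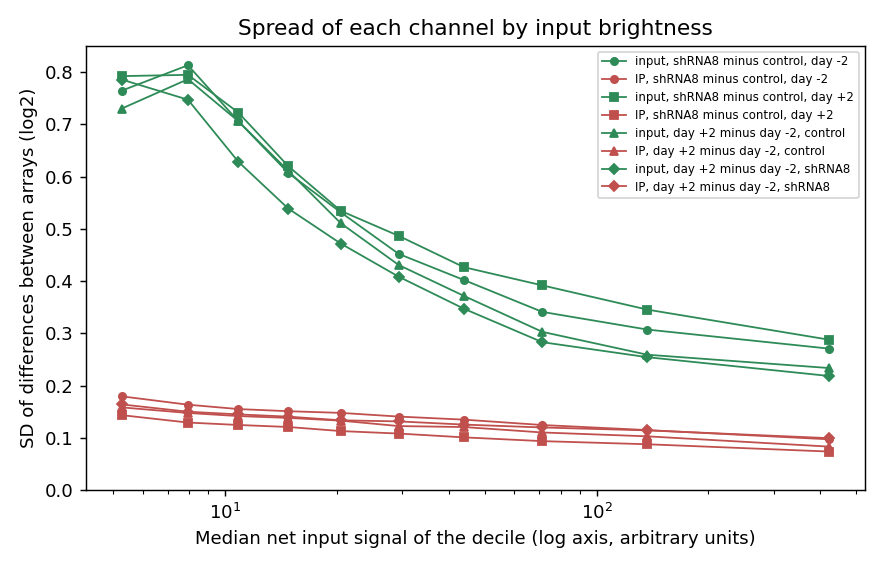
The SD of the differences between arrays (log2, y axis) is plotted for the IP channel (red) and the input channel (green) against the median net input signal of 10 probe classes (log axis), with 1 line for each of the 4 comparisons. Input differences spread more than IP differences at every brightness, and most where the input was dim.

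The comparison of shRNA8 with control cells at day -2 asked how the 2 lines differed before induction. The ratio of IP to input was higher in 206 regions and lower in 218, together 2.43% of the regions. This balance turned to 230 and 217 with median centring alone, 158 and 153 without a filter (1.42% of 21973 regions), 22 and 20 with a size of 1 and 148 and 145 with all probes moving the same way. The size rule used throughout asked for a mean difference of at least 0.6 on the log2 scale and for at least 75% of the probes to move that way. Some regions left out by the share of probes had larger mean differences and are not named. Lower regions gathered near the distal end of chromosome 4, where 6 of the 31 regions between 146 and 148 Mb were lower. On chromosome X, 5 of 9 regions between 144 and 146 Mb were lower, with a mean difference of -0.61. Random placement gave at most 5 lower regions in a window. Within the chromosome 4 window, chr4:146063669-146065201 differed by -1.06 ± 0.26 (SD over 7 probes, all lower). Among regions past the size rule, the differences farthest from 0 rested on probes that disagreed. At chr7:36322324-36323870 the difference was 1.76 ± 3.35 over 4 probes, and at chr17:5491308-5492821 it was -1.67 ± 3.09 over 5 probes.

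In other named regions the spread over probes ranged from a small part of the mean to more than the mean. At chr6:24806985-24807738 the ratio was higher by 1.23 ± 0.81, and at chr11:99733490-99734405 by 1.18 ± 0.60, each over 3 probes. The ratio was also higher at chr1:167864843-167865952 (1.61 ± 2.36), chr4:131429250-131429941 (1.40 ± 1.36), chr5:21370931-21372406 (1.38 ± 1.86), chr8:108103255-108104099 (1.29 ± 1.07) and chr5:28397698-28398166 (1.17 ± 1.07). At chr11:61080350-61081315 the difference was -1.25 ± 0.13 over 3 probes, and it had the opposite sign at day +2. At chr2:86116143-86117888 all 5 probes were lower, with a mean of -1.28 ± 1.19. The remaining named negative differences were at chr18:67019656-67021380 (-1.44 ± 2.64), chr9:39716308-39717783 (-1.34 ± 1.93), chr3:127934434-127935397 (-1.33 ± 1.19), chr5:91831746-91832466 (-1.32 ± 1.55) and chr10:126959208-126960529 (-1.25 ± 1.82). Over these 16 regions the IP channel differed by -0.26 to 0.21 and the input by -2.01 to 1.73.

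When probes were shuffled among regions within 10 classes of input brightness, 100 shuffles gave 320 to 422 regions past the size rule, with a mean of 378, against 424 observed. The 206 higher and 218 lower regions stayed under the shuffled maxima of 229 and 225. The total was 0 for the IP channel alone, 8 without background subtraction and 920 after a within-array loess.

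At day +2, after induction, the same contrast gave 245 higher and 338 lower regions. Lower regions gathered on chromosome 4, with 9 of 31 regions between 146 and 148 Mb and 9 of 22 between 60 and 62 Mb. On chromosome X, 7 of 9 regions between 144 and 146 Mb were lower, with a mean difference of -0.93. Before quantile normalization the input differed there by 0.82 and the IP by 0.09, a smaller gap than in the ratio. Random placement of the lower regions gave at most 8 in a window. In the chromosome 4 windows the mean input difference was 0.24 and 0.49, and the mean IP difference was 0.02 and -0.02. Of the 8 largest negative differences among regions past the size rule, 4 lay between 145 and 148 Mb of chromosome 4. These were chr4:145682677-145684282 (-1.34 ± 0.77 over 6 probes), chr4:146063669-146065201 (-1.29 ± 0.68 over 7), chr4:146926098-146927491 (-1.24 ± 0.59 over 6) and chr4:147016118-147017560 (-1.24 ± 0.58 over 6), and every probe in them was lower.

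Elsewhere, chr4:73328609-73329827 differed by -1.37 ± 0.95 over 5 probes and chrX:146217981-146219419 by -1.24 ± 0.05 over 3. The other named negative differences were at chr7:115666984-115667438 (-1.26 ± 0.22) and chr3:138077483-138078853 (-1.19 ± 0.67). Among regions past the size rule, the largest positive difference was 2.06 ± 2.10 over 3 probes at chr17:39979980-39980438, a ratio 4.16-fold higher in shRNA8 cells. All 4 probes were higher at chrX:8267484-8268634 (1.18 ± 0.78), and all 3 at chr2:86990949-86991782 (1.24 ± 0.63). The size of the difference varied more over the probes at chr2:106810113-106810983 (1.63 ± 1.70), chr14:103745606-103746764 (1.63 ± 3.05), chr6:72566690-72567181 (1.30 ± 1.54), chr11:94188035-94189661 (1.20 ± 2.26) and chrX:160346069-160347059 (1.14 ± 2.00).

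The 583 regions compare with 426 to 508 in the shuffles, whose mean was 462, with at most 253 higher and 287 lower against the 245 and 338 observed. The total was 0 for the IP channel alone, 14 without background subtraction and 1152 after a within-array loess, and removing the trend on the level gave 196 higher and 418 lower regions.

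**Figure D2:**
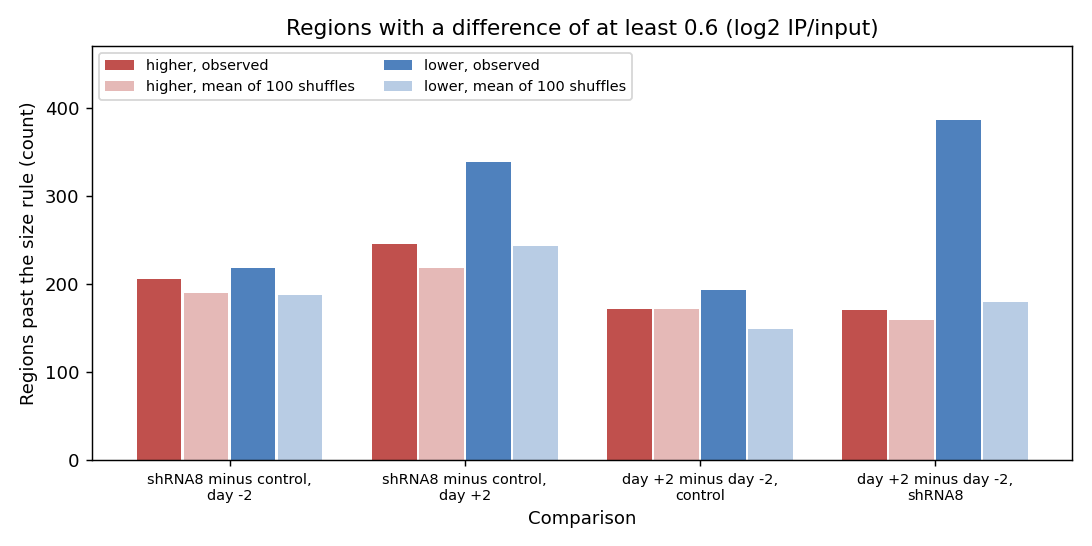
Bars give the number of regions past the size rule (y axis, from 0) in each comparison, higher in red and lower in blue, with the mean of 100 shuffles in the paler colour. The lower regions of shRNA8 cells between the days, 386, stand farthest above their shuffled mean of 179.

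In control cells the day +2 against day -2 comparison asked what changed with induction in unmodified cells. The ratio was higher in 172 regions and lower in 193. Lower regions clustered on chromosome 2, where 8 of 21 regions between 176 and 178 Mb were lower, against at most 7 in any window of 2 Mb when the lower regions were placed at random. At chr2:176265474-176266778 all 6 probes were lower, by -1.11 ± 0.35, with an input change of 1.14 and an IP change of -0.05. Among regions past the size rule, the most negative others were chr17:39979980-39980438 (-1.75 ± 0.71), chr11:61080350-61081315 (-1.28 ± 0.44) and chr6:72566690-72567181 (-1.17 ± 1.32). The most positive regions past the size rule were chr3:138077483-138078853 (1.64 ± 1.22), chr10:117993084-117994828 (1.58 ± 2.22), chr1:121809550-121810354 (1.34 ± 1.82) and chr2:24804668-24805677 (1.29 ± 1.78).

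The 365 regions compare with 276 to 357 in the shuffles, with a mean of 321, and at most 203 higher and 170 lower. The balance turned to 191 higher and 178 lower with the trend on the level removed, 204 and 170 with that on probe length removed, 15 and 12 with a size of 1, and 21 and 13 with input well above background. The total was 0 for the IP channel alone, 1 without background subtraction (chr17:39979980-39980438) and 923 after a within-array loess.

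In shRNA8 cells the same days differed in more regions, 171 higher and 386 lower. The lower ones lay in blocks. On chromosome 2, 13 of 32 regions between 174 and 176 Mb and 16 of 21 between 176 and 178 Mb were lower, and on chromosome 7 this held for 8 of 30 between 6 and 8 Mb and 13 of 14 between 8 and 10 Mb. Chromosome 4 had 12 of 22 lower regions between 60 and 62 Mb and 10 of 31 between 146 and 148 Mb, and chromosome 5 had 8 of 12 between 14 and 16 Mb and 8 of 13 between 26 and 28 Mb. These 8 windows held 88 of the 386 lower regions and no higher one, and random placement gave at most 7 lower regions in a window. The windows were defined after the values were seen.

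Over the 21 regions of chromosome 2 between 176 and 178 Mb the mean ratio changed by -0.80 in shRNA8 cells and by -0.47 in control cells. The input changed by 0.76 and 0.48, and the IP by 0.03 and -0.06. These channel values were centred on each array's median but not quantile normalized. They leave a smaller gap between the lines than the quantile normalized ratio does. Over the 14 regions of chromosome 7 between 8 and 10 Mb the ratio changed by -0.98 in shRNA8 cells and by -0.40 in control cells. The 4 most negative regions past the size rule were chr7:10638028-10639653 (-1.65 ± 0.69 over 6 probes), chr3:93858581-93859588 (-1.64 ± 0.53 over 3), chr2:104429588-104431048 (-1.54 ± 2.59 over 4) and chr2:175294521-175295918 (-1.46 ± 0.56 over 6). The 4 most positive past it were chr17:7998160-7999111 (1.86 ± 3.59), chr18:67019656-67021380 (1.76 ± 3.74), chr11:6167240-6168912 (1.40 ± 2.75) and chr12:30817409-30818389 (1.23 ± 1.17), with an SD over probes close to or above the mean in each.

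The 557 regions compare with 300 to 382 in the shuffles, with a mean of 339, with at most 184 higher and 212 lower against the 171 and 386 observed. The total was 0 for the IP channel alone, 9 without background subtraction and 959 after a within-array loess, which gave 417 higher and 542 lower regions.

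**Figure D3:**
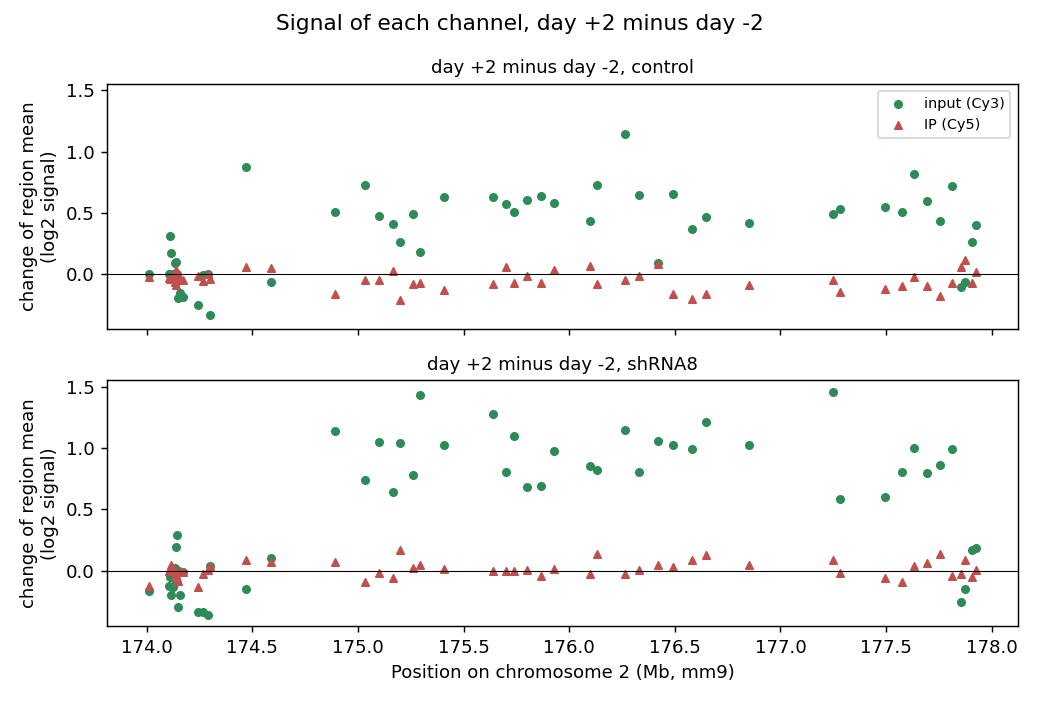
Each region of chromosome 2 between 174 and 178 Mb (x axis, mm9) is drawn with the change of its mean log2 signal from day -2 to day +2 (y axis), for input (green circles) and IP (red triangles), in control cells above and in shRNA8 cells below. Input is higher at day +2 in the regions between 175 and 177 Mb in both lines, with means of 0.76 in shRNA8 and 0.48 in control cells between 176 and 178 Mb, while the IP points stay near 0.

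Whether the line difference was the same at both days was examined across all regions, since the differences at day -2 and day +2 share no array. They correlated with Pearson's r of 0.194 and Spearman's rho of 0.191 across the 17452 regions, which are not independent replicates, and with r of -0.059 for the IP channel alone. Line differences with the days crossed also share no array, but they are built from the same 4 arrays. Their covariance is that of the line differences minus that of the day changes, so they give no independent reference. They correlated with r of 0.084, with 21 regions lower in both (6.48 for independent lists), 5 higher in both (3.19) and 49 opposite (9.43). The ratio was lower in shRNA8 cells at both days in 37 regions, against 4.22 for independent lists, and higher at both days in 9, against 2.89. These counts were 77 and 43 after a within-array loess, 28 and 4 without a filter, 9 and 0 with input well above background, and 0 and 0 both without background subtraction and for the IP channel alone. The higher ones numbered 5 with the trend on the level or on probe length removed. Opposite differences occurred in 8 regions, against 7.05. Of the 37 regions, those with the largest differences at both days were chr4:146063669-146065201 (-1.06 and -1.29), chr10:117182929-117184436 (-0.99 and -1.02), chr13:102001002-102002389 (-0.980 and -0.997), chr4:145206217-145207392 (-0.96 and -1.05), chr7:33614385-33615872 (-0.88 and -0.96) and chr10:116718836-116720407 (-0.87 and -1.12). Of the 9 higher regions, the first 6 were chr11:99733490-99734405 (1.18 and 0.81), chrX:91611231-91612743 (1.02 and 0.80), chr16:91688580-91690150 (0.93 and 0.76), chr3:123211178-123211839 (0.77 and 0.71), chr5:64483895-64484594 (0.70 and 0.69) and chr3:38106542-38108142 (0.68 and 0.71).

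**Figure D4:**
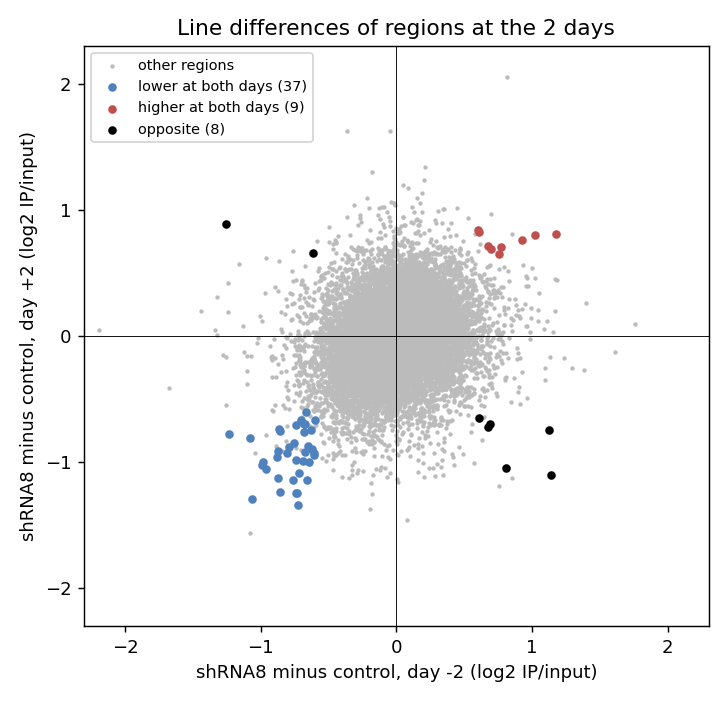
Each point is a region, with the shRNA8 minus control difference at day -2 (x axis, log2 of IP over input) and at day +2 (y axis). Blue points are the 37 regions lower at both days, red points the 9 higher at both days and black points the 8 with opposite differences.

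The day change was also compared between the lines. It was lower in both lines in 51 regions, against 4.27 for independent lists, and higher in both in 6, against 1.69, with r of 0.113 across regions. Here and for the line differences, independent lists treat all regions alike, although regions with a low ratio were called lower more often in every comparison. In the block windows, which were chosen on such calls, r of the day changes was 0.613 over 175 regions. Over the other 17277 regions it was 0.082.

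The difference between the day changes of the 2 lines passed the size rule in 1012 regions, 481 higher and 531 lower in shRNA8 cells, a balance that turned to 1196 and 1124 with a size of 0.4 and 294 and 290 with all probes moving the same way. Shuffled probes gave 905 to 1047 such regions, so the total lay within the shuffles. It was 1 for the IP channel alone, 24 without background subtraction, 87 with input well above background and 1591 after a within-array loess. It draws on all 4 arrays and their errors, and with 4 arrays it leaves no degree of freedom for a test. Chosen after the values were seen, the extremes among these regions were chr11:61080350-61081315, which changed by 0.86 in shRNA8 and -1.28 in control cells (in control cells 0.011 without background subtraction and -0.447 without a filter), and chr3:93858581-93859588, which changed by -1.64 in shRNA8 and 0.60 in control cells.

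The log2 ratio itself correlated with r of 0.050 to 0.072 between adjacent probes up to 500 bp apart in the 4 arrays. The correlation between the differences of such probes was 0.013 between the lines at day -2, 0.046 between the lines at day +2, 0.020 between the days in control cells and 0.071 between the days in shRNA8 cells, over 61916 pairs. Pairs shuffled 100 times gave at most 0.011. By channel these correlations were 0.004 to 0.039 in IP and 0.014 to 0.060 in input. Probe length itself correlated with 0.292 between adjacent probes, a link that shuffling breaks. Between the days the median ratio of 60 bp probes moved from -1.23 to -1.49 in shRNA8 cells and stayed at -1.35 in control cells. An effect of length shared by neighbours was therefore not set apart from a signal shared along the genome.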

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

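The tests of DNA copies and of a change in methylated DNA were chosen after the results were seen, and the test of input brightness before.

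Differences of opposite sign past the size rule were found in 10 regions, between the lines at the 2 days or between the days in the 2 lines, and with 1 array per group the difference itself was not tested. The value given is the day change in shRNA8 cells minus that in control cells. It was -1.86 at chr1:121809550-121810354, -1.87 at chr10:117993084-117994828, -1.26 at chr11:48864913-48865420, 2.15 at chr11:61080350-61081315, 1.27 at chr19:10055077-10055544, -1.38 at chr2:111995449-111996367, -2.24 at chr3:93858581-93859588, -1.39 at chr4:151572933-151574237, 1.67 at chr1:136258086-136258597 and -1.30 at chr15:101362761-101364357. Independent lists would give 7.05 opposite regions between the lines, where 8 were seen, and 5.70 between the days, where 4 were seen.

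The channel labelled as input differed over whole megabases. Among 1631 bins of 1 Mb with at least 15 probes, the median input difference exceeded that of all 100 shuffles in 4 bins between the lines at day +2, in 3 bins between the days in control cells and in 14 bins between the days in shRNA8 cells. The largest medians were 1.03 at 144 to 145 Mb of chromosome X between the lines at day +2, 0.57 at 26 to 27 Mb of chromosome 5 between the days in control cells, and 1.06 at 176 to 177 Mb of chromosome 2 between the days in shRNA8 cells. In each of these bins the input was the brighter at day +2 or in shRNA8 cells, and none lay below the shuffles.

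These blocks had more input signal in shRNA8 cells at day +2 than in the array it was compared with. Both comparisons share the array of shRNA8 cells at day +2, whose input label names that day but describes cells before induction. Not all blocks were brighter than in control cells at day +2. In the chromosome 2 windows the input differed between the lines by -0.0001 (174 to 176 Mb) and 0.06 (176 to 178 Mb) at day +2, and by -0.13 and -0.23 at day -2. On chromosome 7 between 8 and 10 Mb it differed by 0.30 at day +2 and -0.17 at day -2. A gain of DNA copies would raise IP and input together, but in the 4 bins between the lines and the 14 between the days in shRNA8 cells, chosen on input alone, the median IP difference was at most 0.094 of the input difference. This leaves a gain of copies open, since the IP channel, with r of 0.998 to 0.999 between arrays, was not shown to register a change in copies. Mean levels of the 8 block windows ran from -2.35 (chromosome 7, 8 to 10 Mb) to -0.49 (chromosome 7, 6 to 8 Mb). The level was -2.28 on chromosome 2 between 176 and 178 Mb. Probes that match several places in the genome may explain a shared response, but the files hold 0 columns of probe sequence, so this stays open. A change with induction also stays open. Between the days the input of control cells rose by 0.17 to 0.48 in the windows on chromosomes 2, 5 and 7. On chromosome 4 it rose by 0.11 in both windows, against 0.49 (60 to 62 Mb) and 0.20 (146 to 148 Mb) in shRNA8 cells.

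The input channel varied between arrays 3.80 to 5.13 times as much as the IP channel. Repeat spots of one control probe within an array also varied more in input, with SDs of 0.26 to 0.64 against 0.12 to 0.14 in IP. Line and day play no part in that spread. Low brightness of the input was tested on 1092 probes of like brightness in both channels (100 to 400 net, medians of 179 and 191). The SD of the input differences was still 2.29 to 4.06 times that of the IP differences there, so brightness alone does not account for the excess among them. IP was brighter in general, with array medians of 48.9 to 56.5 against 5.95 to 8.78, so these probes had low ratios. Regions of low ratio were called lower more often, so the result may not hold for other probes. With the dyes as labelled, a change in methylated DNA with line or day would move IP more than input. The ratio of 3.80 or more in every comparison cannot decide this. It is the excess itself, and spot noise in input raises it whether or not methylation changed at some regions. A change in methylated DNA therefore stays open. Whether IP and input were exchanged between the dyes cannot be told apart from the labelled assignment without probe sequences, of which the files hold 0 columns. Use of one IP DNA on several arrays was not tested and also stays open, and it would make each difference in the ratio one of the input.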

How the results depend on the processing

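No fit with line or day as a block was run. The alternatives of the stricter filter, median signals, trends on probe length and input brightness, the IP channel alone and the brightest 20% of probes were chosen after seeing the data. Counts are given for the lines at day -2, the lines at day +2, the days in control cells, the days in shRNA8 cells and the difference between day changes, in that order, with 424, 583, 365, 557 and 1012 as reported. They stayed within 1.5 times under median centring alone, scaling to one median absolute deviation, the deposited log ratio, no filter, the median of probes, autosomes alone and the trends on level, length and brightness. Requiring all probes to move the same way did so too, except for the difference between day changes (584). They were 920, 1152, 923, 959 and 1591 after a within-array loess, and 8, 14, 1, 9 and 24 from median signals without background subtraction. They were 40, 91, 34, 95 and 87 with input well above background, among 9485 regions in place of 17452. The IP channel alone gave 0, 0, 0, 0 and 1, the last being chr5:109726284-109727644. A size of 0.6 lies far beyond the SD of 0.11 to 0.14 of the IP differences, so these counts do not show that IP was unchanged. Stricter or looser rules gave 109, 187, 111, 236 and 332 with at least 5 probes, 42, 62, 27, 91 and 171 with a size of 1, and 1412, 1796, 1297, 1451 and 2320 with a size of 0.4, as their construction implies. The cause of the other shifts was not tested. Signals without background subtraction keep an input background of 22 to 26, over which the median net signal was 5.95 to 8.78. Differences in their ratio are smaller by construction for dim probes, so a size of 0.6 is a stricter rule there.

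The share of higher regions between the days in shRNA8 cells was 30.7% as reported, 43.5% after the loess, 16.9% with at least 5 probes, 14.3% with a size of 1, 45.3% with a size of 0.4 and 11.6% with input well above background, and an exchange of IP and input would make it 69.3%. Between the lines at day +2 it was 42.0% as reported, 31.9% without the trend on the level, 28.9% with at least 5 probes, 15.4% with input well above background, 21.4% without background subtraction, 47.4% with median centring alone, 47.7% after the loess or with all probes moving the same way, and 49.1% with a size of 0.4, and an exchange would make it 58.0%. The correlation of the line differences across regions, 0.194, was 0.158 after the loess, 0.163 without a filter, 0.214 without background subtraction, 0.342 with input well above background, 0.334 in the brightest 20% of probes and -0.059 for the IP channel alone, where it turned. Probe correlations at 500 to 2000 bp were 0.014 between the lines at day -2, not below the adjacent 0.013, and 0.028 between the lines at day +2, 0.010 between the days in control cells and 0.024 in shRNA8 cells. Differences of named regions were computed 432 times under 6 alternatives, and 383 moved by less than the SD over probes, 48 by more, and 1 changed sign. Without background subtraction 27 of 72 moved by more than that SD and 54 of 72 fell under 0.6, against 12 without a filter, 1 with centring alone and 0 under the other 3. The sign changed at chr11:61080350-61081315 between the days in control cells without background subtraction (0.011). The planned correction for base composition, mean spot signals, gene lists, named genes' promoters and location classes were not run. The dim input, with a median net signal of 5.95 to 8.78 over a background of 22 to 26, limits every ratio.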

Other observations

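The tests of methylated DNA and of the slide order were chosen after the result was seen, and that of input brightness before.

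Regions where IP was low relative to input stood apart. The level was taken from the 2 arrays outside each comparison. Of 559 regions with a mean level at or under -2, 19.3% were lower at day +2 in shRNA8 cells, against 1.65% of the 16893 other regions. The shares were 7.69% and 0.88% between the days in control cells, 5.64% and 1.1% between the lines at day -2, and 8.60% and 1.73% at day +2. Higher regions made up 1.61% and 0.96%, 1.54% and 0.97%, 1.71% and 1.16%, and 2.24% and 1.38%, in the same order. This split was made with quantile normalization only, which can itself move regions of low level. On chromosome 2 between 176 and 178 Mb the mean ratio differed by -0.22 between the lines at day +2. The input differed there by 0.06 and the IP by -0.002. Among the 51 regions lower with the day in both lines, 10 lay between 175 and 178 Mb of chromosome 2, 6 between 7 and 10 Mb of chromosome 7 and 5 between 3 and 6 Mb of chromosome X. Among the 37 regions lower in shRNA8 cells at both days, 8 lay between 145 and 148 Mb of chromosome 4 and 5 between 144 and 147 Mb of chromosome X.

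The line difference of the ratio recurred at both days (r = 0.194 across regions), but that of the IP channel alone did not (r = -0.059). The IP channel held -0.025 of the covariance of the differences at the 2 days (95% bootstrap interval over regions -0.030 to -0.020) and input 1.12. The recurrence was thus carried by the channel labelled as input. The bootstrap interval treats regions as independent, although neighbouring regions changed together in blocks. It leaves out the variation between arrays and between cultures. A line difference in methylated DNA stays open, since the IP channel was not shown to register one and the channels may have been exchanged. A trend of the ratio with input brightness is argued against, since the correlation kept 0.970 of its value once that trend was removed. The same-probe correlation rose from 0.085 in the dimmest to 0.365 in the brightest of 5 classes of input, so dim probes may hide part of the recurrence. The order of the arrays on the slide cannot be told apart from the line, as 0 arrays of shRNA8 cells lay past a control array, and a lasting difference of the lines in input DNA stays open.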
